A study of Arabidopsis thaliana with 12 samples.

How the data were processed

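RNA-seq was analysed in 12 libraries of Arabidopsis thaliana root tips, 3 biological replicates in each of 4 groups: Col-0 and the scl5 scl21 pat1 triple mutant, each on control medium or after bleomycin. Per the labels' protocols, RNA was extracted with a QIAGEN RNeasy Plant Mini kit and libraries were prepared with a NEBNext Ultra kit, which is named without a strand-marking version. The labels call the replicates biological, and p-values measure the spread between these samples. The submitters' processing notes name Salmon 0.9.1, a transcript quantifier, and CASAVA with no role. The genome build, the annotation and the Salmon options are not given in the sources used here, so no coordinates are printed.

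The authors deposited 1 Salmon table per library with 88971 transcripts, and, per the file headers, an estimated read count, a TPM value and an effective length for each. The estimated counts deposited by the authors need not be whole, and at least 36.4% of those above 0 were whole in each library. The TPM values deposited by the authors are transcript abundances corrected for length and scaled to one total over all listed transcripts. The effective lengths, per the file headers, are transcript lengths in bases as Salmon corrects them. No sample-wide normalization, filter or pooling was seen in these tables. Of the transcripts, 30576 belong to transposable elements, which held 0.067% to 0.091% of the reads and were left out of the comparisons and tested separately.

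Estimated counts were summed per gene and rounded to whole numbers, which gave 37138 loci. Of these, 36899 were matched by locus code in a table of RefSeq genes of assembly TAIR10.1, used for names, product descriptions and neighbouring genes, and 10559 carry a symbol other than the code; the unmatched 239 are organelle loci. Totals were 36.3 to 40.9 M reads per library, and the ribosomal RNA locus AT3G41768 took 0.81% to 5.14% of them. A floor of 3 reads corresponded to 0.0734 to 0.0827 CPM in 1 library. Folds against a group with 0 reads were computed against 3 reads over that group, and ratios with 1 to 3 reads carry an exact 95% interval; intervals and floors cover counting error only. Salmon assigns reads shared by near-identical or overlapping genes by estimation, so such genes are uncertain. Counts of replicates differed beyond sampling noise in each group (chi-square over degrees of freedom 18.7 to 101.8), so no library was counted as a copy of another.

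The following choices were made before the data were examined. Differential expression was tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test, with TMM scaling and the filterByExpr filter by group (21561 genes). A single model was fitted over all 12 libraries with group as the only term. Adjustment followed Benjamini-Hochberg at 0.05 with no fold threshold. A gene that passed is called. The common biological coefficient of variation was 0.30. The 5 comparisons were bleomycin against control in each genotype, triple mutant against Col-0 in each medium, and their interaction. For a single gene, unadjusted p-values are named as such.

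Also fixed beforehand were 25 gene lists with 421 entries for 402 genes, all found in the RefSeq table and 363 under the same name. Those of the cell cycle and DNA were DNA damage response, recombination and end joining repair, mitosis and cytokinesis, DNA replication, histone H3, D-type cyclins, CDK inhibitors and cell cycle transcription factors. The others were GRAS factors, DOF factors, wound-induced regeneration, stem cell niche, and markers of root cap, epidermis and root hair, endodermis, xylem, phloem and photosynthesis. Also included were developmental cell death, jasmonate, ethylene, auxin, cytokinin, xenobiotic detoxification, and salicylic acid with camalexin. They were tested with camera in limma 3.58.1 with a preset inter-gene correlation of 0.01, adjusted over the 25 lists of a comparison, and again with the correlation estimated. With an estimated correlation the damage response and wound lists held in Col-0, the damage response list in the triple mutant, the GRAS list in control, and the GRAS and wound lists after bleomycin. With DOF3.4 left out as well, the wound list was not called in Col-0 (adjusted p = 0.0795). After bleomycin it was at 0.0854, in a run that also took the mutated genes out of the GRAS list. The loss of the GRAS call changes the adjustment there, so 0.0854 does not show the effect of DOF3.4 alone. Of the 125 list tests the median, the mean and the test differed in sign in 20, none of them with an adjusted p under 0.05.

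The rule for named genes was fixed too. PAT1, SCL5, SCL21, DOF3.4, ERF115 and CYCD3;3 are given in each comparison. So are the 6 called genes with the largest fitted rise and the 6 with the largest fall among those with at least 2 CPM on average over the groups compared and no overlap between their libraries. For each list with a camera adjusted p under 0.05, or with at least 25% of its measured members called, up to 3 called members with the smallest p in the main direction and 1 in the other are named. The damage response, mitosis, wound and DOF lists are described in each comparison, and tissue markers at least as counts. Where few genes outside this rule were called, they are named and said to be chosen after their values were seen; the values of some genes are not reported here.

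The replicate numbers come from the sample titles, which do not say what a number marks. Deviations of same-numbered libraries from their group means correlated at 0.47, 0.24 and 0.28 between the bleomycin groups of both genotypes, above 0.1 in each pair, so the blocked value is given beside that comparison. The other comparisons did not meet this in each pair.

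On simulated counts for the 21561 genes, with 200 of them changed, the test recovered 45% of 2-fold and 73% of 4-fold changes for bleomycin in Col-0 and 45% and 82% in the triple mutant. It recovered 46% and 69% for the genotype in control, 50% and 77% for the genotype after bleomycin, and 16% and 59% for the interaction. Between 3.3% and 6.6% of its calls were false. The simulation drew each gene independently, with no effect of replicate number and no library that stands apart. Its shares of recovered and false calls therefore need not hold for the real libraries. The alternatives were DESeq2 1.42.0, limma voom, DESeq2's size factors or upper-quartile scaling in edgeR, no filter or at least 10 CPM in 3 libraries, the replicate block, and only the libraries compared. Further ones were an offset from effective lengths, limma-trend on log2(TPM + 1), omission of organelle genes, a fold threshold of 1.5, and each library left out in turn. For lists they were an estimated correlation, the self-contained test fry, which tests a list against no change and not against other genes, the block and each library left out. Chosen after seeing the data were the omission of ribosomal RNA loci, inclusion of transposable elements, limma voom with sample weights, and lists without the mutated genes or without DOF3.4. The mutated genes and DOF3.4 were left out of their lists in the same run, so its adjusted p-values carry both removals. Ranges over alternatives in the text cover all of these that gave a value for the result, each otherwise changed alone. Moderated log2 CPM used a prior count of 2.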

Results

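Transcript levels were measured by RNA-seq in root tips of Arabidopsis thaliana, cut at 0.2 cm, from the wild-type accession Col-0 and from a triple mutant of SCL5, SCL21 and PAT1, genes for transcriptional regulators of the GRAS family. Seedlings on nylon mesh, about 100 seeds per sample, were moved 7 days after sowing to control medium or to medium with 0.5 µg/ml bleomycin, a drug that breaks DNA strands, and were treated for 24 h. The title of the series connects PAT1-type GRAS proteins with regeneration after wounding, the transcription factor gene DOF3.4 and cell proliferation. Each of the 4 groups held 3 biological replicates, named here by group and number, such as Col-0 control 1. The libraries held 40.9, 36.6 and 39.1 M reads in Col-0 control, 40.4, 38.2 and 37.6 M in Col-0 bleomycin, 36.3, 38.1 and 38.6 M in triple mutant control, and 37.9, 40.3 and 39.7 M in triple mutant bleomycin. Levels are read counts scaled to library size (CPM), given as mean ± SD over the 3 libraries of a group, and 21561 genes were abundant enough to be tested. A fold against a group with 0 reads is a lower bound against 3 reads summed over that group.

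The first principal component of log2 CPM held 34.3% of the variance and placed the bleomycin libraries at 23.9 to 73.1 and the control libraries below 0. Triple mutant control 3 stood apart at -125.9 on it and at -102.7 on the second component (17.6%), while the other control libraries lay between -64.3 and -5.0 on the first. Among genes with at least 10 reads in each of the other libraries, 381 had 0 reads in triple mutant control 3, against at most 35 in any other library examined in that way. Some gene lists differed between libraries by their replicate number. Relative to the mean of all libraries, the median log2 CPM of photosynthesis markers was lowest in library 3 of each group, at -0.53 and -0.75 in Col-0 control and bleomycin and -1.36 and -0.82 in the triple mutant. It was highest in library 1 of each group, at 0.75, 0.64, 0.69 and 0.37. Endodermis markers were highest in library 1 of each group too, at 0.30, 0.76, 0.16 and 0.81, against -0.86 and -0.72 in Col-0 controls 2 and 3. For xylem markers Col-0 control 1 was at 0.45, against -0.52 and -0.73 in Col-0 controls 2 and 3.

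The mutated genes were read first in every library. SCL5 (AT1G50600) stood at 36 ± 1.6 CPM in Col-0 control and 40.6 ± 4.2 in Col-0 bleomycin, while the triple mutant held 1 read in the control libraries and 2 in the bleomycin libraries. SCL21 (AT2G04890) had 12.5, 12.4 and 9.6 CPM in Col-0 control, 12.1, 14.8 and 10.2 in Col-0 bleomycin, and 0 reads in each of the 6 triple mutant libraries. PAT1 (AT5G48150) was lower in the triple mutant but remained present, with 9.34, 9.53 and 9.73 CPM in control and 10.2, 16.9 and 9.77 in bleomycin, against 26.1, 26.0 and 25.5, and 36.1, 43.3 and 34.3, in Col-0. All 12 libraries thus carried the pattern of their genotype label.

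**Figure D1:**
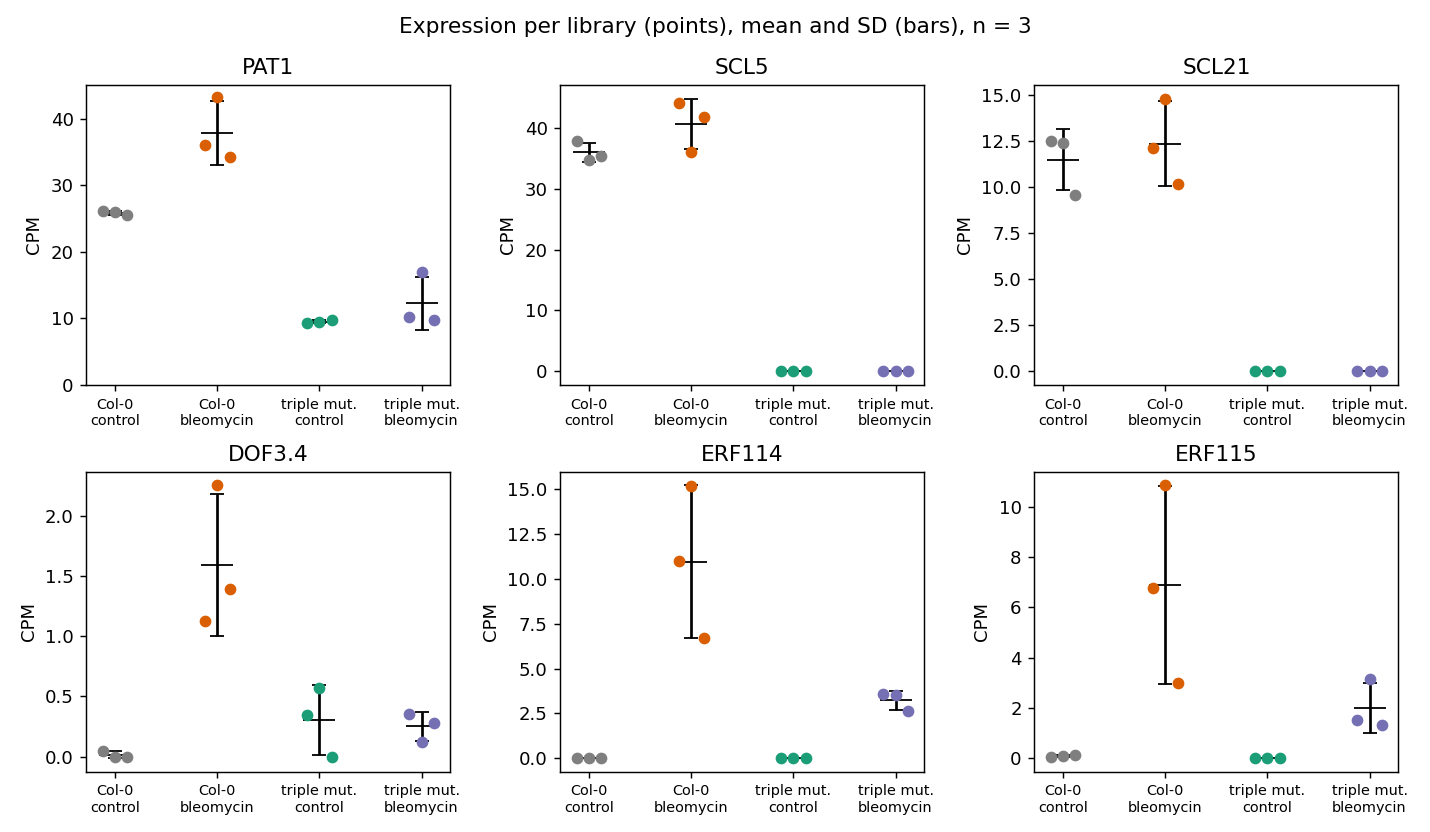
Read counts scaled to library size (CPM) in each library for PAT1, SCL5, SCL21, DOF3.4, ERF114 and ERF115; points are single libraries and bars are the mean with its SD, n = 3 per group. SCL21 is at 0 in each triple mutant library, PAT1 keeps 9.34 to 16.9 CPM there, and DOF3.4 reaches 1.13 to 2.25 CPM in Col-0 bleomycin against at most 0.357 in triple mutant bleomycin.

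Bleomycin in Col-0 raised genes of the DNA damage response, the list with the highest median change of the 25 fixed before the data were examined. Of the 30 measured members 25 rose and 0 fell, both over all genes and adjusted over the list alone, with a median log2 fold change of 1.88. Its camera adjusted p was 2.8e-87 and its adjusted p was 0.00050 with an estimated correlation, in a range of 2.7e-99 to 0.00050 over the alternatives. TSO2 (AT3G27060), a small subunit of ribonucleotide reductase, rose from 60.1 ± 5.1 to 478 ± 60 CPM (log2 fold change 2.99, SE 0.15, edgeR adjusted p = 3.6e-07). PARP2 (AT4G02390), a poly(ADP-ribose) polymerase, rose from 16.1 ± 1.9 to 130 ± 21 CPM (3.01, SE 0.19, 2.9e-06). SMR7 (AT3G27630), an inhibitor of cyclin-dependent kinases, rose from 0.391 ± 0.10 to 51.0 ± 11 CPM (7.01, SE 0.45, 2.9e-06). The list shares ERF115 with the wound list, BRCA1 among others with the repair list, TSO2 and RNR1 with the replication list, and SMR4, SMR5, SMR7 and KRP6 with the inhibitor list. Over all genes 1455 were called by edgeR's quasi-likelihood test, 925 higher and 530 lower, of which 558 changed more than 2-fold. The count was 356 without Col-0 control 2, 434 without Col-0 control 3, 584 without Col-0 bleomycin 1 and 831 without Col-0 bleomycin 2.

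The largest rises in Col-0 were in genes with few or no control reads. ABCA10 (AT5G61740), an ABC transporter gene, went from 0 reads to 15.0 ± 6.7 CPM, at least 594-fold higher (edgeR adjusted p = 3.3e-05). ERF114 (AT5G61890), an ethylene response factor gene, went from 0 reads to 11 ± 4.3 CPM, at least 433-fold (4.8e-05), and DRM1 (AT5G15380), annotated as domains rearranged methylase 1, from 0 reads to 6.38 ± 2.0 CPM, at least 252-fold (0.0029). AT4G25330, annotated as a SAWADEE protein, and AT2G25370, annotated with a RING/U-box domain, rose from 0 reads to 4.17 ± 1.9 and 4.03 ± 2.3 CPM, at least 165-fold and 160-fold. AT1G20750, annotated as a RAD3-like helicase, had 2 control reads, in Col-0 control 1, and 29.4 ± 12 CPM after bleomycin (ratio 1745, 95% counting interval 483 to 14417, edgeR adjusted p = 6.2e-05). Its adjusted p was 0.0903 with limma voom, the highest of its alternatives, whose lowest was 1.4e-09; without Col-0 control 1 its control group was at 0 reads.

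The largest falls in Col-0 included the copper/zinc superoxide dismutase genes CSD1 and CSD2. CSD1 (AT1G08830) fell from 345 ± 90 to 47.9 ± 10 CPM (log2 fold change -2.85, SE 0.26, edgeR adjusted p = 4.3e-05) and CSD2 (AT2G28190) from 138 ± 15 to 22.2 ± 3.5 CPM (-2.63, SE 0.19, 4.6e-06). ATGSTF13 (AT3G62760), a glutathione transferase gene, fell from 11.5 ± 4.0 to 1.24 ± 0.55 CPM (-3.21, SE 0.46, 0.0018). NRPD2B (AT3G18090), annotated as an RNA polymerase subunit, fell from 5.98 ± 2.5 to 1.07 ± 0.24 CPM (-2.47, SE 0.47, 0.0096). ENODL13 (AT5G25090), an early nodulin-like gene, fell from 17.9 ± 6.3 to 3.3 ± 2.3 (-2.45, SE 0.51, 0.015) and AT2G26330, a leucine-rich repeat receptor-like kinase gene, from 5.39 ± 2.2 to 0.82 ± 0.61 (-2.72, SE 0.59, 0.019). NRPD2B was not called without Col-0 control 3 (edgeR adjusted p = 0.0514, the highest of its alternatives; lowest 7.3e-06). ENODL13 was not called without Col-0 control 2 (0.0508), Col-0 control 3 (0.0713) or Col-0 bleomycin 2 (0.051), in a range of 1.1e-05 to 0.0713, and its log2 fold change was -3.08 without Col-0 bleomycin 3. AT2G26330 was not called without Col-0 control 2 (0.0615) or Col-0 control 3 (0.0841), in a range of 6.0e-05 to 0.0841, and its log2 fold change was -3.39 without Col-0 bleomycin 2.

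Genes of mitosis and cytokinesis lay lower after bleomycin in Col-0, by small amounts. In this list 35 of 38 measured members had a log2 fold change below 0, with a median of -0.46 (camera adjusted p = 3.0e-07), and 2 fell over all genes and 2 adjusted over the list alone. The list was not called with an estimated correlation (adjusted p = 0.493, range over the alternatives 3.0e-13 to 0.493). CYCA2;3 (AT1G15570), an A-type cyclin, fell from 33.0 ± 2.3 to 22.4 ± 1.2 CPM (log2 fold change -0.56, SE 0.11, edgeR adjusted p = 0.012). POK1 (AT3G17360), a kinesin that guides the division plane, fell from 34.3 ± 1.3 to 21.6 ± 0.97 CPM (-0.67, SE 0.17, 0.038). Per library, the list median relative to all libraries was 0.13 in Col-0 bleomycin 3 and 0.20 in triple mutant bleomycin 3, against -0.49 to -0.24 in the other bleomycin libraries and 0.17 to 0.31 in the controls. CYCA2;3 was not called without Col-0 control 2 (0.0764) or Col-0 bleomycin 1 (0.0539), in a range of 0.00047 to 1. POK1 was not called without Col-0 control 2 (0.144), Col-0 control 3 (0.112), Col-0 bleomycin 1 (0.102), 2 (0.093) or 3 (0.0687), or triple mutant bleomycin 1 (0.0518), in a range of 0.0040 to 1.

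Inhibitors of cyclin-dependent kinases moved mainly upward in Col-0, 5 of 21 rising and 1 falling, or 6 and 1 adjusted over the list alone (median log2 fold change 0.18, camera adjusted p = 0.012). The list was not called with an estimated correlation (adjusted p = 0.158, range 0.0022 to 0.199) or without Col-0 control 1 (0.0524). SMR5 (AT1G07500) went from 0 reads to 2.00 ± 0.53 CPM, at least 78.9-fold (edgeR adjusted p = 0.0015). SMR1 (AT3G10525) rose from 28.6 ± 1.8 to 46.8 ± 6.5 CPM (log2 fold change 0.71, SE 0.13, 0.0068), while KRP3 (AT5G48820) fell from 7.88 ± 1.8 to 3.48 ± 0.62 CPM (-1.18, SE 0.24, 0.015). KRP3 was not called without Col-0 control 2 (0.0717) or Col-0 control 3 (0.0769), in a range of 0.00025 to 0.195, and SMR1 only against a fold of 1.5 (0.869, lowest 4.5e-05). Replication-dependent histone H3 genes had a median of -0.44 over 5 members (camera adjusted p = 0.025), 0 called over all genes and 3 lower adjusted over the list alone. That list was not called with an estimated correlation (adjusted p = 0.493, range 0.00086 to 0.493) or without Col-0 bleomycin 2 (0.0791). No D-type cyclin of 9 and no cell cycle transcription factor of 11 was called (camera adjusted p = 0.98 and 0.37). CYCD3;3 (AT3G50070) was at 31.5 ± 5.7 and 24.4 ± 3.0 CPM (log2 fold change -0.37, SE 0.16, edgeR adjusted p = 0.166). Of 23 replication genes TSO2 and RNR1 rose and FEN1 fell (camera adjusted p = 0.37), and of 25 recombination and end joining genes 3 rose, BRCA1 and RAD54 among them (0.37); FEN1 and RAD54 are named after their values were seen. Adjusted over the list alone, 1 recombination gene and 1 cell cycle transcription factor were lower as well.

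Some genes linked to regeneration after wounding rose in Col-0. Of the 25 measured members 7 were called higher and 0 lower, or 11 and 0 adjusted over the list alone, with a median log2 fold change of 0.60. The camera adjusted p was 1.0e-05, against an adjusted p of 0.044 with an estimated correlation, the highest of the alternatives, whose lowest was 5.3e-06. With DOF3.4 left out as well as an estimated correlation, the adjusted p was 0.0795 and the call was lost. ERF115 (AT5G07310), an ethylene response factor gene of wounded and damaged root cells, rose from 0.085 ± 0.039 to 6.87 ± 3.9 CPM (log2 fold change 6.28, SE 0.71, edgeR adjusted p = 0.00068). ERF114 rose as above, and RAP2.6L (AT5G13330) rose from 15.1 ± 1.3 to 26.8 ± 0.11 CPM (0.83, SE 0.15, 0.0066). DOF3.4 (AT3G50410) had 2, 0 and 0 reads in the controls and 45, 89 and 52 after bleomycin, 1.59 ± 0.59 CPM, a ratio of 93.7 (95% counting interval 25.6 to 779, edgeR adjusted p = 0.029). It was the only called gene among 11 DOF factors (median 0.22, camera adjusted p = 0.37; 1 adjusted over the list alone). The call of DOF3.4 was lost without Col-0 control 2 (0.134), Col-0 control 3 (0.115), Col-0 bleomycin 1 (0.0663), 2 (0.0695) or 3 (0.053), in a range of 0.00023 to 0.134. Without Col-0 control 1 its control group was at 0 reads. RAP2.6L was not called against a fold of 1.5 (0.486, lowest 3.7e-05). Of the 3 GRAS genes, SCL5 had a log2 fold change of 0.18 (SE 0.20, edgeR adjusted p = 0.64), SCL21 of 0.10 (SE 0.25, 0.85) and PAT1 of 0.55 (SE 0.18, 0.089). PAT1 passed under 5 of 27 alternatives, among them DESeq2 (0.0483), the replicate block (0.0356) and the fit without triple mutant bleomycin 2 (0.0229), in a range of 0.0176 to 1. No member of the GRAS list was called (0 of 16, camera adjusted p = 0.62).

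Some genes of cell death, detoxification and defence rose after bleomycin in Col-0. All 8 markers of developmental cell death lay above 0 (camera adjusted p = 0.0022; adjusted p = 0.361 with an estimated correlation, range 0.00015 to 0.361). Per library, relative to all libraries, their median was 0.01, -0.56 and -0.42 in Col-0 control and 0.75, 0.06 and 0.43 in Col-0 bleomycin. That of xylem markers was 0.45, -0.52 and -0.73, and 1.1, 0.04 and 0.45, in the same libraries. RNS3 (AT1G26820), a ribonuclease gene, and SCPL48 (AT3G45010), a carboxypeptidase gene, were called over all genes and 3 adjusted over the list alone. RNS3 rose from 33.2 ± 6.4 to 51.7 ± 4.9 CPM (log2 fold change 0.64, SE 0.15, edgeR adjusted p = 0.026) and SCPL48 from 35.3 ± 9.4 to 62.2 ± 13 (0.82, SE 0.21, 0.037). Of 17 detoxification genes 4 rose, 7 adjusted over the list alone, with a median of 0.50 (camera adjusted p = 1.0e-05; adjusted p = 0.179 with an estimated correlation, range 8.5e-08 to 0.179). The glutathione transferases GSTU22 (AT1G78340) and GSTU25 (AT1G17180) rose from 124 ± 30 to 291 ± 31 CPM (1.23, SE 0.16, 0.0007) and from 478 ± 137 to 1218 ± 267 CPM (1.35, SE 0.19, 0.0018). GSTU8 (AT3G09270) rose from 129 ± 14 to 206 ± 19 (0.68, SE 0.14, 0.013). In the salicylic acid and camalexin list PAD3 (AT3G26830), a cytochrome P450 of camalexin synthesis, rose from 0.97 ± 0.46 to 13.6 ± 1.6 CPM (3.81, SE 0.36, 5.3e-05). It was the only member of 11 called over all genes, and 5 were higher and 1 lower adjusted over the list alone (median 0.74, camera adjusted p = 0.00098; adjusted p = 0.11 with an estimated correlation, range 0.00014 to 0.11). RNS3 was not called without Col-0 control 2 (0.134), Col-0 control 3 (0.122) or Col-0 bleomycin 1 (0.0952), in a range of 0.0023 to 1. SCPL48 was not called without Col-0 control 2 (0.163), Col-0 control 3 (0.142), Col-0 bleomycin 1 (0.138), Col-0 bleomycin 3 (0.0578) or triple mutant control 1 (0.0505), in a range of 0.0024 to 0.804. GSTU8 was not called without Col-0 control 2 (0.0836) or Col-0 control 3 (0.0525), in a range of 0.00014 to 1.

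The remaining lists passed no camera test in Col-0, and genes called in them that are named were chosen after their values were seen. For tissue markers, BRN2 rose among 7 root cap markers (camera adjusted p = 0.995), LRX1 among 9 epidermis and root hair markers (0.051), and OPS among 10 phloem markers (0.37). ACL5 fell among 11 xylem markers (0.16), and 0 were called of 9 endodermis (0.12) and 10 photosynthesis markers (0.61). The endodermis and xylem medians were 0.69 and 0.71, and Col-0 control 1 lay above the other Col-0 controls for both lists. In the auxin list IAA5, IAA29, ARF5 and GH3.3 rose and PIN4 fell of 29 measured (0.057), with 8 higher and 1 lower adjusted over the list alone. Of 14 ethylene genes 1 rose (0.11), and 0 were called of 17 jasmonate (0.83), 23 cytokinin (0.12) and 13 stem cell niche genes (0.075, median -0.31). The jasmonate list median differed between Col-0 bleomycin libraries 1, 2 and 3, at -0.72, 1.47 and 0.21. Adjusted over the list alone these counts were unchanged, apart from 2 higher and 1 lower among root cap markers and the auxin genes above.

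Bleomycin in the triple mutant raised the same list of damage response genes. Of 30 members 24 rose and 0 fell, and 24 rose adjusted over the list alone, with a median log2 fold change of 2.02. Its camera adjusted p was 4.0e-88 (adjusted p = 0.00035 with an estimated correlation, range 2.9e-95 to 0.00035). TSO2 rose from 64.5 ± 5.1 to 487 ± 84 CPM (log2 fold change 2.91, SE 0.15, edgeR adjusted p = 8.2e-07) and PARP2 from 16.5 ± 2.8 to 131 ± 27 CPM (2.99, SE 0.19, 3.0e-06). SMR7 rose from 0.235 ± 0.21 to 50.3 ± 9.7 CPM (7.74, SE 0.48, 2.3e-06). WEE1 was the member called in Col-0 but not here, and its interaction was not called (log2 fold change -0.53). SMR7 had a log2 fold change of 8.35 without triple mutant control 2 and of 7.13 without triple mutant control 3. In all 1727 genes were called, 905 higher and 822 lower, of which 541 changed more than 2-fold. The count was 510 without triple mutant bleomycin 1, 596 without triple mutant bleomycin 2, 612 without triple mutant control 2 and 932 without triple mutant control 3.

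Largest rises and falls in the triple mutant overlapped in part with those in Col-0. AT2G24255, annotated as an F-box/kelch protein, and AT4G25330 went from 0 reads to 6.33 ± 2.6 and 4.42 ± 1.4 CPM, at least 239-fold (edgeR adjusted p = 0.0023) and at least 165-fold. ABCA10 and AT3G28510, annotated as a nucleoside triphosphatase, each had 2 control reads, all in triple mutant control 2, and 14.4 ± 5.6 and 4.51 ± 1.2 CPM after bleomycin. Their ratios were 809 (95% counting interval 224 to 6690) and 252 (69.4 to 2085), and without triple mutant control 2 both control groups were at 0 reads. AT1G20750 rose from 0.216 ± 0.33 to 25.8 ± 12 CPM (log2 fold change 6.84, SE 0.76, edgeR adjusted p = 0.00024), with a log2 fold change of 9.72 without triple mutant control 3. With limma voom ABCA10 had an adjusted p of 0.0612 and AT1G20750 of 0.0859, the highest of alternatives that began at 1.1e-15 and 2.3e-06. CSD1 fell from 347 ± 107 to 61.2 ± 12 CPM (-2.50, SE 0.26, 0.00014) and ENODL13 from 19.4 ± 2.9 to 2.85 ± 1.5 (-2.77, SE 0.52, 0.0089). AT3G15720, a pectin lyase-like gene, fell from 17.2 ± 3.5 to 2.94 ± 1.8 (-2.55, SE 0.42, 0.0048). CYP78A9 (AT3G61880), a cytochrome P450 gene, fell from 4.24 ± 0.81 to 0.74 ± 0.33 (-2.52, SE 0.47, 0.0089) and AT3G01295 from 4.33 ± 1.9 to 0.69 ± 0.27 (-2.64, SE 0.52, 0.011). AT3G15720 had a log2 fold change of -3.17 without triple mutant bleomycin 3. AT3G01295 was not called without triple mutant bleomycin 1 (0.0523) or 2 (0.0519), in a range of 2.0e-05 to 0.0523. The GRAS family gene AT1G07520 fell from 6.72 ± 5.7 to 0.346 ± 0.56 CPM (-4.30, SE 1.19, 0.043). It was not called without Col-0 control 2 (0.0599), Col-0 bleomycin 3 (0.0562), triple mutant control 2 (0.15) or 3 (0.0625), or triple mutant bleomycin 2 (0.13) or 3 (0.0806), in a range of 0.014 to 0.225. Its log2 fold change was -3.34 without triple mutant control 2, -7.91 without triple mutant bleomycin 1 and -3.71 without triple mutant bleomycin 3.

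Of the cell cycle lists, mitosis and histone H3 genes passed the camera test in the triple mutant, and neither held with an estimated correlation. Of 38 mitosis genes 35 lay below 0, with a median of -0.41 (camera adjusted p = 0.00012; adjusted p = 0.687 with an estimated correlation, range 5.3e-09 to 0.687). CYCA2;3 was the only 1 called over all genes, falling from 31.8 ± 1.8 to 23.6 ± 1.8 CPM (log2 fold change -0.43, SE 0.11, edgeR adjusted p = 0.034), with 0 adjusted over the list alone. POK1 was at 22.7 ± 6.1 and 20.5 ± 2.2 CPM. CYCA2;3 was not called without triple mutant control 1 (0.0806), 2 (0.0626) or 3 (0.0787) or triple mutant bleomycin 1 (0.146) or 2 (0.0893), in a range of 0.011 to 1. Of 5 histone H3 genes HTR13 (AT5G10390) fell from 46.6 ± 9.4 to 27.8 ± 6.1 CPM (-0.75, SE 0.20, 0.041), and 3 fell adjusted over the list alone. The list median was -0.43 (camera adjusted p = 0.033; adjusted p = 0.655 with an estimated correlation, range 0.013 to 0.655). HTR13 was not called without Col-0 control 3 (0.0557), triple mutant control 2 (0.0981) or 3 (0.129), or triple mutant bleomycin 1 (0.115) or 2 (0.133), in a range of 0.0083 to 0.932. The H3 list was not called without triple mutant control 2 (0.0539) or 3 (0.0558) or triple mutant bleomycin 2 (0.129).

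Among 21 kinase inhibitors in the triple mutant 5 rose and 1 fell, or 5 and 3 adjusted over the list alone (camera adjusted p = 0.25). SMR5 went from 0 reads to 2.92 ± 1.0 CPM, at least 109-fold (edgeR adjusted p = 0.0013). SMR4 (AT5G02220) rose from 2.34 ± 1.7 to 9.25 ± 0.56 CPM (log2 fold change 1.98, SE 0.47, 0.023), and KRP3 fell from 8.97 ± 0.98 to 3.36 ± 0.38 CPM (-1.42, SE 0.24, 0.0058). SMR4 was not called without triple mutant control 1 (0.0551) or triple mutant bleomycin 1 (0.0747) or 2 (0.0632), in a range of 0.00029 to 0.155, and its log2 fold change was 2.58 without triple mutant control 2. KRP3 was not called against a fold of 1.5 (0.0587, lowest 4.6e-06). No D-type cyclin was called over all genes (camera adjusted p = 0.97), while 2 were lower adjusted over the list alone. CYCD3;3, 1 of the 2, was at 31.5 ± 2.4 and 22.9 ± 3.0 CPM (-0.46, SE 0.16, edgeR adjusted p = 0.087 over all genes, range 0.0319 to 1; 0.048 over the list). Over the list CYCD3;3 was lost without Col-0 control 2 (0.0638) or 3 (0.0552), Col-0 bleomycin 3 (0.06), triple mutant control 1 (0.123), 2 (0.138) or 3 (0.0736), or triple mutant bleomycin 1 (0.148) or 2 (0.198), in a range of 0.019 to 0.996. Over all genes CYCD3;3 passed under 2 of 27 alternatives, the replicate block and limma voom with sample weights. Of replication genes TSO2 and RNR1 rose (camera adjusted p = 0.062). Of repair genes 3 rose and 2 fell, with BRCA1 and RAD54 among the rises and KU70 among the falls (0.38), and no cell cycle transcription factor was called (0.78). KU70 is named after its values were seen, and adjusted over the list alone 3 repair genes were lower.

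Wound and regeneration genes lay mostly above 0 in the triple mutant, with 18 of 25 members above and 7 below, against 19 and 6 in Col-0. ERF114 went from 0 reads to 3.24 ± 0.52 CPM, at least 121-fold (edgeR adjusted p = 0.0002), and ERF115 from 0 reads to 2.00 ± 0.99 CPM, at least 75.6-fold (0.00078; highest of its alternatives 0.0634 with limma voom, lowest 7.4e-09). RAP2.6L rose from 16.7 ± 1.3 to 25.7 ± 5.0 CPM (log2 fold change 0.62, SE 0.15, 0.024). PLT3 (AT5G10510), a PLETHORA factor gene of the root meristem, fell from 67.9 ± 13 to 45.0 ± 7.6 CPM (-0.59, SE 0.16, 0.037). These were the 3 rises and 1 fall among 25 members, or 4 and 1 adjusted over the list alone (median 0.31, camera adjusted p = 0.033; adjusted p = 0.606 with an estimated correlation, range 0.0072 to 0.606). The list was not called without triple mutant control 1 (0.0764) or 2 (0.0907) or triple mutant bleomycin 2 (0.0616). RAP2.6L was not called without triple mutant control 1 (0.0629) or 2 (0.0903) or triple mutant bleomycin 2 (0.0965), in a range of 0.0039 to 1. PLT3 was not called without triple mutant control 2 (0.141) or 3 (0.07) or triple mutant bleomycin 1 (0.15) or 2 (0.107), in a range of 0.0080 to 1.

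DOF3.4 had 12, 22 and 0 reads in triple mutant control and 13, 5 and 11 after bleomycin, 0.305 ± 0.29 and 0.252 ± 0.12 CPM (log2 fold change -0.28, SE 1.17, edgeR adjusted p = 0.91). The library with 0 reads was triple mutant control 3, which stood apart with 381 genes at 0 reads, so the control mean of DOF3.4 is uncertain. Of 11 DOF genes HCA2 (AT5G62940) rose, from 0.749 ± 0.34 to 2.86 ± 0.73 CPM (1.93, SE 0.52, 0.041; 1 adjusted over the list alone; camera adjusted p = 0.97). HCA2 was not called without Col-0 control 2 (0.0576), Col-0 bleomycin 2 (0.0507), triple mutant control 1 (0.0569), 2 (0.0968) or 3 (0.0967), or triple mutant bleomycin 1 (0.123) or 2 (0.117), in a range of 0.0037 to 0.276. PAT1 had a log2 fold change of 0.37 (SE 0.19, edgeR adjusted p = 0.25), SCL5 had 1 and 2 reads and SCL21 had 0. Stem cell niche genes had a median of -0.33 over 13 members, of which PLT3 was called (camera adjusted p = 0.033; adjusted p = 0.655 with an estimated correlation, range 0.017 to 0.655). This list was not called without triple mutant control 2 (0.0955) or triple mutant bleomycin 1 (0.0671) or 2 (0.0646).

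Some detoxification genes and a defence gene rose in the triple mutant too. GSTU22 rose from 150 ± 10 to 288 ± 25 CPM (log2 fold change 0.94, SE 0.16, edgeR adjusted p = 0.0049) and GSTU25 from 572 ± 9.2 to 1268 ± 73 (1.15, SE 0.19, 0.0051). GSTU1 (AT2G29490) rose from 113 ± 7.4 to 148 ± 2.7 (0.39, SE 0.10, 0.037). These were the 3 of 17 called, against 4 adjusted over the list alone (median 0.26, camera adjusted p = 0.023; adjusted p = 0.655 with an estimated correlation, range 0.0059 to 0.655; 0.0907 without triple mutant control 2). PAD3, the only 1 of 11 defence genes called, rose from 1.25 ± 0.36 to 13.8 ± 3.0 CPM (3.47, SE 0.36, 0.00013; 1 adjusted over the list alone). The list median was 0.48 (camera adjusted p = 0.041; adjusted p = 0.606 with an estimated correlation, range 0.0062 to 0.606). Without Col-0 bleomycin 2 (0.0572) or 3 (0.0524), triple mutant control 1 (0.134) or 2 (0.0963), or triple mutant bleomycin 2 (0.0782), the defence list was not called. All 8 cell death markers lay above 0 (camera adjusted p = 0.033; adjusted p = 0.655 with an estimated correlation, range 0.0068 to 0.655). Their list was not called without triple mutant control 1 (0.0764) or 2 (0.0955) or triple mutant bleomycin 2 (0.0705). Xylem markers had a median of 0.67 beside them, with a camera adjusted p of 0.57. SCPL48 rose from 31.1 ± 5.8 to 53.9 ± 8.4 CPM (0.79, SE 0.21, 0.037), with 2 adjusted over the list alone. SCPL48 was not called without Col-0 control 3 (0.0505), Col-0 bleomycin 3 (0.051), triple mutant control 1 (0.0833) or 2 (0.141), or triple mutant bleomycin 1 (0.146), 2 (0.0713) or 3 (0.0526), in a range of 0.0027 to 0.829. GSTU1 was not called without Col-0 control 2 (0.0594), triple mutant control 1 (0.0547), 2 (0.113) or 3 (0.122), or triple mutant bleomycin 1 (0.128), 2 (0.0894) or 3 (0.0706), in a range of 0.0040 to 1. Against a fold of 1.5, GSTU22 (0.24, lowest of its alternatives 6.7e-07) and GSTU25 (0.108, lowest 1.5e-07) were not called.

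The tissue and hormone lists passed no camera test in the triple mutant, and genes called in them that are named were chosen after their values were seen. LRX1 rose among epidermis and root hair markers (camera adjusted p = 0.062) and ACL5 fell among xylem markers (0.57). No root cap (0.97), endodermis (0.088), phloem (0.74) or photosynthesis marker (0.57) was called; the photosynthesis median was lowest in triple mutant control 3. Among ethylene genes 1 rose (0.74), IAA29 and GH3.3 rose and YUC3, PIN4 and IAA20 fell among auxin genes (0.94), and 0 jasmonate (0.57), cytokinin (0.81) or GRAS list members (0.97) were called. Adjusted over the list alone, 2 epidermis markers were higher, 2 xylem markers higher and 1 lower, and 1 phloem marker and 1 GRAS gene each were higher and lower; the other counts were unchanged.

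Both genotypes shared 565 genes called higher and 355 called lower after bleomycin, where lists drawn independently would share 39 and 20. Of the 925 genes called higher in Col-0, 918 were also above 0 in the triple mutant, and of the 530 called lower, 528 were below 0. The median log2 fold change of the genes called higher in Col-0 was 1.04 there and 0.81 in the triple mutant, and of those called lower -0.63 and -0.61. For genes called higher in the triple mutant it was 0.94 there and 0.88 in Col-0, and for those called lower -0.66 and -0.51. Choosing genes by their call in a genotype by itself places them farther from 0 in that genotype. Across all tested genes the fold changes correlated with a Pearson r of 0.618 and a Spearman rho of 0.66, computed across genes, which are not independent replicates. The 2 fold changes share no library. Over the 2262 genes called in either genotype r was 0.878. With any 1 library left out, r over the genes tested lay between 0.43, without Col-0 bleomycin 1, and 0.568, without triple mutant control 3. Those fits repeated the filter on low counts and tested 21944 to 22084 genes instead of 21561. The drop from 0.618 therefore mixes the missing library with a changed set of genes.

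**Figure D2:**
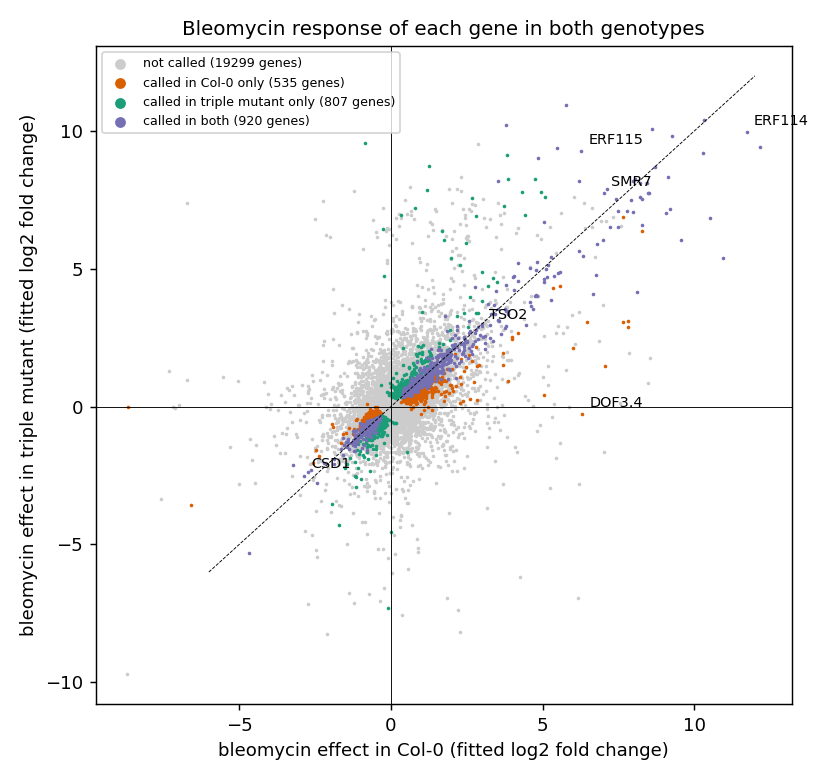
Fitted log2 fold change of each tested gene after bleomycin in Col-0 (horizontal axis) and in the triple mutant (vertical axis); colours mark genes called in both (920), in Col-0 only (535), in the triple mutant only (807) or in neither (19299). Most genes called in either genotype lie on the same side of 0 in both, and the most extreme fitted values belong to genes with a group at or near 0 reads, which depend on the prior count.

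The triple mutant differed from Col-0 under control conditions in the 3 mutated genes, a neighbour of SCL21 and 2 other loci. SCL5 was lower by a ratio of 4034 (4233 reads against 1, 95% counting interval 724 to 1.59e5, edgeR adjusted p = 1.3e-08), its single read lying in triple mutant control 2. SCL21 was at least 430-fold lower (3.4e-05), and PAT1 fell from 25.9 ± 0.31 to 9.53 ± 0.19 CPM (log2 fold change -1.44, SE 0.19, edgeR adjusted p = 0.017). AT2G04900, which overlaps the start of SCL21 on the opposite strand and whose count is therefore uncertain, was at 73.4 ± 6.7 CPM in Col-0 and 0 reads in the triple mutant, at least 2737-fold lower (4.8e-08). AT1G64795, an uncharacterized locus that overlaps ILA and whose count is therefore uncertain, was the only gene called higher, from 1 read to 11.1 ± 3.2 CPM (ratio 1304, 95% counting interval 234 to 51555, 8.9e-05). AT5G33395, named after its values were seen, was the other gene called lower, at 3.01 ± 1.4 and 0.017 ± 0.030 CPM. In all 6 genes were called, 1 higher and 5 lower. PAT1 was not called without Col-0 control 2 (0.102) or 3 (0.0874) or triple mutant control 1 (0.166), 2 (0.176) or 3 (0.12), in a range of 4.6e-08 to 0.176. AT5G33395 was not called without Col-0 control 2 (0.142) or 3 (0.167), Col-0 bleomycin 3 (0.0611), triple mutant control 1 (0.335), 2 (0.283) or 3 (0.428), or triple mutant bleomycin 1 (0.0737), in a range of 4.1e-06 to 0.871. AT1G64795 was not called with limma voom (0.871, lowest of its alternatives 8.2e-13), and its only Col-0 read lay in Col-0 control 1.

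No gene of the damage, mitosis or wound lists was called between the genotypes in control medium. Their list medians were -0.041 for damage response (camera adjusted p = 0.55), -0.0082 for mitosis (0.55) and 0.012 for wound genes (0.95), or 0.020 with genes at 0 reads set to their bound. No gene was called adjusted over each of these lists alone. POK1 was at 34.3 ± 1.3 and 22.7 ± 6.1 CPM (log2 fold change -0.60, SE 0.17, edgeR adjusted p = 0.96), ERF115 at 0.085 ± 0.039 and 0 CPM and CYCD3;3 at 31.5 ± 5.7 and 31.5 ± 2.4 CPM. DOF3.4 had 2 reads against 34, a ratio of 17.8 (95% counting interval 4.57 to 153, edgeR adjusted p = 0.96), and its list had a camera adjusted p of 0.66. The 16 GRAS genes fell as a list (camera adjusted p = 9.4e-23; adjusted p = 0.0023 with an estimated correlation) and held the 3 mutated genes as their only called members. Without these the camera adjusted p was 0.952, the highest of its alternatives, whose lowest was 4.1e-26. Cytokinin genes (median 0.35, camera adjusted p = 0.014), detoxification genes (0.19, 0.016), kinase inhibitors (0.19, 0.042) and auxin genes (0.080, 0.043) lay above the other genes, with 0 members called. With an estimated correlation none of these held (adjusted p = 0.406, 0.724, 0.406 and 0.406), and over the alternatives they ranged from 0.0037 to 0.526, 2.4e-05 to 0.724, 0.00031 to 0.526 and 0.0078 to 0.526. The value of 0.526 came from fry, which tests a list against no change and not against other genes. The cytokinin list was lost without triple mutant control 3 (0.0693), the detoxification list without Col-0 control 2 (0.394) or 3 (0.0633) or triple mutant control 1 (0.105) or 3 (0.0693). The inhibitor list was lost without Col-0 control 1 (0.102), 2 (0.0824) or 3 (0.0633) or triple mutant control 1 (0.158) or 2 (0.272). The auxin list was lost without Col-0 control 2 (0.359) or 3 (0.0927) or triple mutant control 1 (0.105) or 3 (0.0693). Adjusted over the list alone 2 auxin genes, IAA5 and IAA2, were higher (0.042 each). Both were lost without Col-0 control 2 (0.228) or 3 (0.209), Col-0 bleomycin 1 (0.0519) or 2 (0.0505), triple mutant control 1 (0.164) or 2 (0.0858), or triple mutant bleomycin 1 (0.0591) or 2 (0.0526). IAA5 was lost also without Col-0 control 1 (0.0648) or Col-0 bleomycin 3 (0.0506) and IAA2 without triple mutant control 3 (0.0759), in ranges of 0.00041 to 0.477 and 0.0073 to 0.973. The other 16 lists had camera adjusted p-values of at least 0.129 and 0 genes called, the tissue markers among them.

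After bleomycin the triple mutant again differed in SCL5, SCL21, PAT1 and their neighbour, and genes of the wound list lay lower. SCL5 was lower by a ratio of 2377 (4740 reads against 2, 95% counting interval 658 to 19631, edgeR adjusted p = 1.1e-08), both reads lying in triple mutant bleomycin 2. SCL21 was at least 485-fold lower (3.0e-05), and PAT1 was at 37.9 ± 4.8 and 12.3 ± 4.0 CPM (log2 fold change -1.62, SE 0.19, 0.0045). AT2G04900 was lower by a ratio of 5427 (2 reads in the triple mutant, in triple mutant bleomycin 3, 95% counting interval 1502 to 44818, 3.8e-08), and AT1G64795 was at least 552-fold higher (14.0 ± 6.6 CPM, 5.1e-05). AT5G35940, a mannose-binding lectin gene, was at 101 ± 37 and 24.9 ± 5.3 CPM (-2.03, SE 0.27, 0.014). These were the 6 genes called, 1 higher and 5 lower, and with the replicate number as a block 10 were called, 1 higher and 9 lower, including the 6. Without triple mutant control 3 the count was 10. AT5G35940 was not called without Col-0 bleomycin 2 (0.0618) or 3 (0.0512) or triple mutant bleomycin 1 (0.0608), 2 (0.122) or 3 (0.088), in a range of 1.2e-11 to 0.237. PAT1 was not called with the 6 compared libraries alone (0.247, lowest of its alternatives 2.6e-11), and AT1G64795 not with limma voom (0.624, lowest 7.0e-17).

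Regeneration genes lay below their Col-0 level in bleomycin-treated triple mutant tips. In the wound list 18 of 25 members were below 0, with a median of -0.30 (camera adjusted p = 2.5e-07; adjusted p = 0.024 with an estimated correlation; highest of the alternatives 0.0706 with the self-contained test fry, lowest 3.8e-08). With an estimated correlation and DOF3.4 left out, the unadjusted camera p of the wound list was 0.0034, against 0.0019 with DOF3.4 kept. Its adjusted p of 0.0854 came from a run that also took the mutated genes out of the GRAS list, which changes the adjustment. That value therefore does not show whether removing DOF3.4 alone ends the call. Of the marker lists, 10 of 11 for xylem also lay below 0 (median -0.21, camera adjusted p = 0.126), as did 7 of 8 for cell death (-0.20, 0.407). Phloem markers were split evenly, with 5 of 10 below 0 (-0.17, 0.126). In the wound list no member was called over all genes and 4 were lower adjusted over the list alone. These were PLT3 at 73.1 ± 2.1 and 45.0 ± 7.6 CPM (log2 fold change -0.70, SE 0.16, list adjusted p = 0.016) and ERF114 at 11 ± 4.3 and 3.24 ± 0.52 CPM (-1.76, SE 0.38, 0.016), as well as ERF115 at 6.87 ± 3.9 and 2.00 ± 0.99 CPM (-1.78, SE 0.55, 0.0496) and NAC096 (-1.52, SE 0.47, 0.0496). PLT3 was lost without Col-0 bleomycin 1 (0.0504) or 2 (0.0572) or triple mutant bleomycin 1 (0.0554), in a range of 0.00053 to 0.378. ERF114 was lost without Col-0 bleomycin 1 (0.0662) or 2 (0.131) or triple mutant bleomycin 1 (0.0554) or 3 (0.0863), in a range of 0.0003 to 0.131. ERF115 and NAC096 were each lost under 13 of 26 alternatives, 8 of them omissions of 1 library. Both were lost without Col-0 control 1 or 2, Col-0 bleomycin 1 or 2, triple mutant control 2, or triple mutant bleomycin 1 or 3. ERF115 was lost also without Col-0 control 3 and NAC096 without triple mutant bleomycin 2. Their list adjusted p in these fits was 0.0534 to 0.284 and 0.0534 to 0.241, and the lowest of all alternatives was 0.0051 and 0.0068. In the stem cell niche list 10 of 13 members lay below 0, with a median of -0.28 (camera adjusted p = 0.00027; adjusted p = 0.185 with an estimated correlation, range 2.2e-05 to 0.33). Adjusted over the list alone PLT3, a member of both lists, and BBM were lower (0.0083 and 0.022). BBM was lost without Col-0 bleomycin 3 (0.0854) or triple mutant bleomycin 1 (0.0738) or 2 (0.113), and PLT3 without triple mutant bleomycin 1 (0.0539), in ranges of 0.0056 to 0.589 and 0.00051 to 0.589.

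No other list passed between the genotypes after bleomycin, apart from the GRAS list with its 3 mutated members (camera adjusted p = 2.5e-49; 0.978 without them, the highest of its alternatives, lowest 2.8e-50). DOF3.4 was at 1.59 ± 0.59 CPM in Col-0 and 0.252 ± 0.12 in the triple mutant (log2 fold change -2.65, SE 1.2, edgeR adjusted p = 1). Its list had a median of -0.045 and 8 of 11 members below 0 (camera adjusted p = 0.37), with 0 called. The damage response list had a median of 0.015 (0.95) and the mitosis list of 0.025 (0.41), each with 0 genes called, also adjusted over the list alone, and CYCD3;3 had a log2 fold change of -0.09 (SE 0.16). Adjusted over their own list, ARF5 of the auxin list and OPS of the phloem list, named after their values were seen, were lower (0.022 and 0.027). ARF5 was lost without Col-0 bleomycin 1 (0.141) or triple mutant bleomycin 1 (0.153), in a range of 0.0039 to 0.999. OPS was lost without Col-0 bleomycin 1 (0.205) or 3 (0.0591) or triple mutant bleomycin 1 (0.0624) or 2 (0.137), in a range of 0.0075 to 0.988. The remaining lists had camera adjusted p-values of at least 0.126.

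The interaction asked whether the response to bleomycin differed between the genotypes, and no single gene passed. edgeR called 0 genes (lowest adjusted p = 0.99997), 377 had an unadjusted p under 0.05, and DESeq2 and limma voom called 0. DOF3.4 had an unadjusted edgeR p of 0.0040 (adjusted p = 0.99997), with 2 and 186 reads in Col-0 control and bleomycin and 34 and 29 in the triple mutant. It was the 1 of 11 DOF genes called adjusted over the list alone (0.044; list camera adjusted p = 0.23). That call was lost without Col-0 control 2 (0.127) or 3 (0.0935), Col-0 bleomycin 1 (0.0739), 2 (0.0627) or 3 (0.0531), triple mutant control 2 (0.132), or triple mutant bleomycin 1 (0.0831), 2 (0.0702) or 3 (0.0967), in a range of 0.0016 to 0.139 over all alternatives. PAT1 had an interaction of -0.18 (SE 0.26), CYCD3;3 of -0.09 (SE 0.22), and ERF115 and the 2 other mutated genes had a group at or near 0 reads. The damage response list had a median interaction of 0.042 (camera adjusted p = 0.52) and the mitosis list of 0.10 (0.23), with 0 called.

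Taken as lists, 4 groups of genes had interactions below those of other genes by the camera test, that is, a lower response in the triple mutant, with 0 members called over all genes or over the list alone. Cytokinin genes had a median interaction of -0.33, with 18 of 23 below 0 (camera adjusted p = 0.0039; adjusted p = 0.306 with an estimated correlation), and auxin genes -0.26, with 22 of 29 (0.0060; 0.306). Wound genes had -0.23, with 19 of 25 (0.023; 0.306 with an estimated correlation) and detoxification genes -0.16, with 16 of 17 (0.023; 0.715). None thus held with an estimated correlation. The highest adjusted p of each list came from fry, which tests a list against no change and not against other genes, and over the alternatives the adjusted p ranged from 4.1e-05 to 0.749, 0.0003 to 0.749, 0.0074 to 0.749 and 3.9e-05 to 0.983. The wound list, which holds DOF3.4, was at 0.139 without that gene. It was lost without Col-0 control 2 (0.131) or 3 (0.12), Col-0 bleomycin 1 (0.0701) or 2 (0.293), triple mutant control 3 (0.0984), or triple mutant bleomycin 1 (0.084) or 3 (0.0664). The cytokinin list was lost without Col-0 bleomycin 2 (0.146), and the auxin list without Col-0 control 2 (0.111), Col-0 bleomycin 3 (0.0517) or triple mutant bleomycin 1 (0.0526). The detoxification list was lost without Col-0 control 2 (0.32) or 3 (0.114), Col-0 bleomycin 3 (0.309), triple mutant control 1 (0.139) or 3 (0.0984), or triple mutant bleomycin 1 (0.0526) or 3 (0.0589). The other lists, tissue markers included, had camera adjusted p-values of at least 0.189 and 0 genes called. Cytokinin, auxin and detoxification genes lay higher in the triple mutant in control (medians 0.35, 0.080 and 0.19, camera adjusted p = 0.014, 0.043 and 0.016). After bleomycin their genotype medians were -0.083, -0.048 and -0.025 (camera adjusted p = 0.41, 0.37 and 0.95). Their interactions thus reflect the control libraries at least in part. Wound genes had 0.012 in control and -0.30 after bleomycin.

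**Figure D3:**
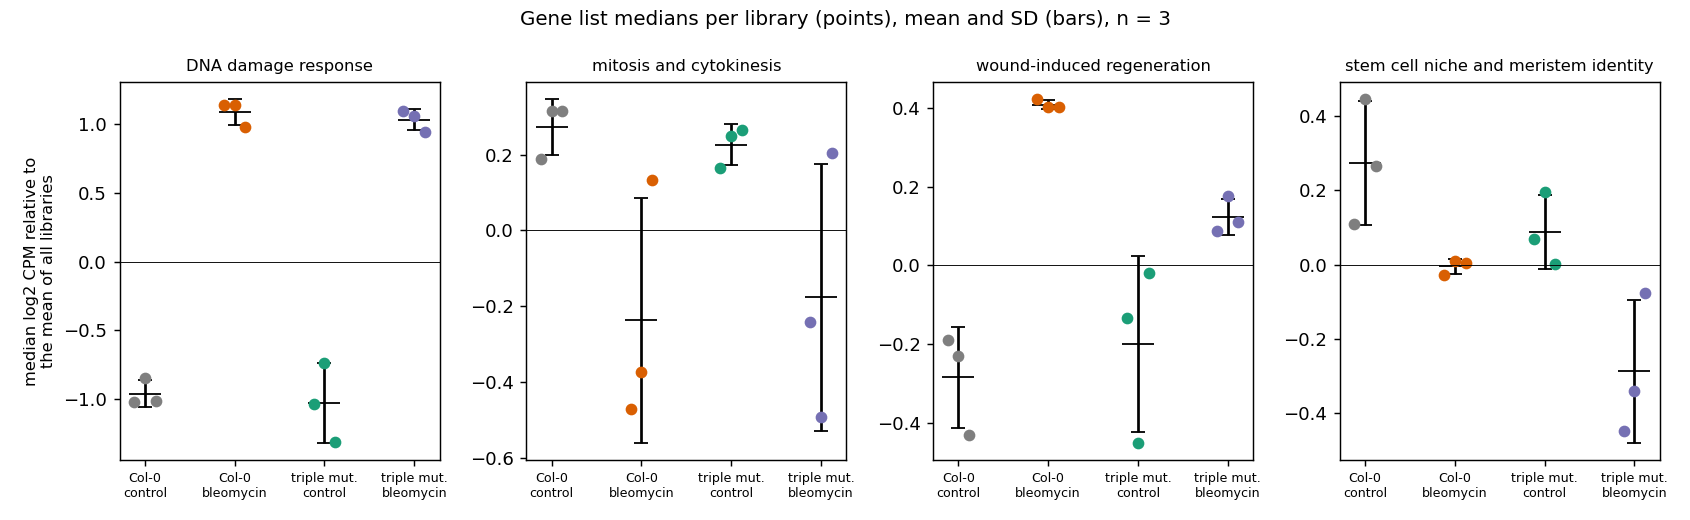
Median log2 CPM of the damage response, mitosis, wound and stem cell niche lists in each library, relative to the mean of all libraries; points are single libraries and lines with error bars are the group mean and SD (n = 3). The damage response median separates bleomycin from control in both genotypes, while the mitosis median of the bleomycin libraries numbered 3, at 0.13 and 0.20, lies near the controls.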

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

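The list tests below were chosen before the data were examined; the test of transposable element loci, left out of the comparisons, was chosen only after the files had been read.

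By a camera test of the interaction with a preset correlation, the response to bleomycin was lower in the triple mutant for 4 lists, but none held with an estimated correlation (adjusted p = 0.306, 0.306, 0.306 and 0.715) or with the fry test. The lists were cytokinin (camera adjusted p = 0.0039, median interaction -0.33), auxin (0.0060, -0.26), wound-induced regeneration (0.023, -0.23) and xenobiotic detoxification (0.023, -0.16). In each, most members had an interaction below 0, 18 of 23, 22 of 29, 19 of 25 and 16 of 17, and 0 members were called. Over the alternatives their adjusted p ranged up to 0.749, 0.749, 0.749 and 0.983. For cytokinin, auxin and detoxification genes the triple mutant lay higher in control (medians 0.35, 0.080 and 0.19). After bleomycin the genotype medians of these lists were -0.083, -0.048 and -0.025. No explanation was tested.

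Transposable element transcripts rose at single loci after bleomycin. Of 362 loci abundant enough to be tested, 1 was called in Col-0 and 7 in the triple mutant, 6 higher and 1 lower, and 0 in the other 3 comparisons. AT5TE45925 was called in both, at 3.35 ± 1.7 CPM against 0.284 in Col-0 control (edgeR adjusted p = 0.022) and at 2.02 ± 0.65 CPM against 0.136 in triple mutant control (0.017). Over all 21561 genes 1455 and 1727 were called in Col-0 and the triple mutant, a larger share than of these loci. AT1TE71950, AT1TE88160 and AT3TE02890, called in the triple mutant, had 0 reads in its controls and 1.24, 0.73 and 0.27 CPM after bleomycin.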

How the results depend on the processing

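The omission of ribosomal RNA loci, the inclusion of transposable elements, sample weights, and the lists without mutated genes or DOF3.4 were chosen only after the data had been seen; the other alternatives were fixed before. For single named genes 2231 results kept their side of the threshold, 153 lost and 7 gained a call. Where the main or the alternative fit called the gene, 0 reversed in direction. A change of sign in a result called by neither fit was not counted. For lists, all of them called in the main test, 349 results kept their direction and call, 104 lost the call and 1 reversed. The reversed result was the GRAS list in control without the 3 mutated genes (camera adjusted p = 0.952), as its called members were those genes. The fold threshold of 1.5 ended most gene calls (26), but it tests against a change of that size and cannot call smaller fitted changes. It was followed by the fit on only the 6 libraries compared (14), which has fewer libraries to estimate the spread. Next came the fits without Col-0 control 2 (13), Col-0 control 3 (12) or triple mutant bleomycin 2 (11). For lists an estimated correlation and fry ended most.

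For bleomycin in Col-0 the count of 1455 became 2748 with DESeq2 (1723 higher, 1025 lower), which included 1453 of the 1455, and 3883 with voom and sample weights. It was 825 with only the 6 libraries compared (630 and 195), 895 on log2(TPM + 1) (808 and 87), and 197 against a fold of 1.5 (185 and 12). For the triple mutant the count of 1727 became 2863 with DESeq2 (1570 and 1293), 2990 with voom and sample weights, 813 on log2(TPM + 1) (693 and 120), and 167 against a fold of 1.5 (152 and 15). DESeq2 called 25 genes for the genotype in control (9 higher, 16 lower) and 23 after bleomycin (4 and 19), where 10 were called with no filter and 11 on log2(TPM + 1) (1 and 10). The interaction count was 0 under each alternative. Leaving out 1 library gave 356 (without Col-0 control 2) to 2081 (without Col-0 control 1) genes in Col-0, 510 (without triple mutant bleomycin 1) to 1853 (without Col-0 control 1) in the triple mutant. It gave 4 to 9 for the genotype in control and 5 to 10 after bleomycin. The share of higher calls, 63.6% in Col-0 and 52.4% in the triple mutant, moved to 57.7% and 48.0% with upper-quartile and 65.5% and 53.2% with median-ratio scaling, while the median of all genes shifted by at most 0.026 (log2). The correlation of the responses, 0.618, was 0.878 over called genes, 0.885 with at least 10 CPM, and 0.43 to 0.568 without 1 library. Each of these values was computed over another set of genes than the main value. Apart from stated constructions, the cause of these changes was not tested.

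Called lists numbered 2 in Col-0, 1 in the triple mutant, 1 and 2 for the genotype in control and after bleomycin, and 0 for the interaction with an estimated correlation, against 8, 8, 5, 3 and 4. With fry they numbered 3 in the triple mutant, 1 for each genotype comparison and 0 for the interaction. Leaving out 1 library gave 8 to 12, 2 to 10 (2 without triple mutant control 2), 2 to 8 (8 without Col-0 control 1), 3 to 6 and 1 to 10 (10 without Col-0 control 1). The replicate block, for which only the genotype after bleomycin passed the pairing check in each pair, gave 10 genes there. In the other comparisons, where the titles give only a number, not every pair passed that check, and deviations correlated at 0.39, 0.13 and 0.07 in Col-0, 0.17, 0.03 and 0.09 in the triple mutant and 0.15, 0.06 and 0.12 in control. Some shared structure by number was still seen there, as 4 of 6, 6 of 6 and 6 of 6 libraries correlated best with their own number. The main fit does not take it into account. The block gave 3437 genes in Col-0 (2050 higher, 1387 lower), 3633 in the triple mutant (1939 and 1694), 8 for the genotype in control and 0 for the interaction, and 11, 8, 3, 3 and 4 lists. Depth limits genes such as DOF3.4, with at most 89 reads in a library. The simulated test recovered 16% of 2-fold interactions, so a count of 0 there does not exclude changes of that size.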

Other observations

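The tests of gene families, of scaling by opposite directions, of triple mutant control 3 and of the locus beside SCL21 were chosen only after the result was seen. The copper and iron lists were written after CSD1, CSD2 and a member of the copper shortage list had been seen, but before their other members were. The splits of the samples were planned.

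Ribosomal protein genes lay lower after bleomycin in both genotypes. Of 324 measured, 104 fell and 4 rose in Col-0 (median log2 fold change -0.45) and 194 fell and 3 rose in the triple mutant (-0.57); RPS15 went from 887 to 602 CPM and from 910 to 602 CPM. In Col-0 and the triple mutant, 10 and 10 of 53 peroxidases rose (medians 0.84 and 0.81), 7 and 9 of 52 pectin methylesterases and their inhibitors, and 14 and 10 of 130 cytochromes P450, of which 0 and 2 fell. So did 12 and 5 of 108 UDP-glycosyltransferases, and 13 and 22 of 157 extensins and proline-rich proteins, of which 3 fell in each. Of 171 receptor-like kinases 8 and 9 rose and 4 and 3 fell. Over all 21561 genes 925 and 905 were called higher and 530 and 822 lower. The rises of receptor-like kinases, and of UDP-glycosyltransferases in the triple mutant, were thus near the share of all genes. Of 73 NAC factors 13 and 10 rose, and of 57 WRKY factors 9 and 4. These families were among 24 picked by product description after the results were seen. The camera adjusted p of ribosomal proteins was 7.0e-34 and 1.1e-49, but none of the 24 passed with an estimated correlation, where the lowest adjusted p was 0.139 in Col-0 and 0.197 in the triple mutant.

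Copper-responsive genes changed together with the fall of CSD1 and CSD2. Of 13 measured genes that copper shortage induces, 10 rose in each genotype, 9 of them in both. In Col-0 FSD1 went from 101 ± 52 to 745 ± 66 CPM, CCH from 207 to 678, COPT2 from 2.3 to 76.6 ± 21 and CITF1 from 2.66 to 36.1. Lower copper availability is a candidate explanation, since bleomycin binds copper: of 12 members not seen before the list was written 9 rose in each genotype, 8 in both (medians 2.91 and 2.99; larger p with an estimated correlation 0.0035). The unseen members of a list of copper proteins and microRNA targets were 2 of 5 lower in each (medians -0.27 and -0.04). Their camera p was 0.047 and 0.051 and, with an estimated correlation, 0.077 and 0.082. The other members were not called: LAC3 and LAC7 lay above 0 (log2 fold change 0.27 and 2.66 in Col-0, 0.42 and 2.38 in the triple mutant). LAC13 lay at -0.27 and -0.04. Scaling alone would move all genes alike, but the induced list had a median of at least 2.95 in both genotypes while CSD1 and CSD2 fell; 2 other scalings, which left CSD1 and CSD2 at -2.3 or lower, moved the median of all genes by at most 0.026 and could not test it. Iron shortage was not settled: its list had medians of 0.43 and 0.10, less than it predicted but above 0, with 1 of 15 genes called in each genotype (camera p 0.041 and 0.215; with an estimated correlation 0.286 and 0.513). Whether the drug, the damage or another difference of the media acts on copper genes was not tested, so this remains a hypothesis.

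Triple mutant control 3 stood apart by 381 genes at 0 reads. Lower depth was excluded, with 38.63 M reads against 36.3 in the shallowest library, and shoot tissue too, with photosynthesis markers at -1.36. Low library complexity, first tested as a rise in both tails against all libraries, was counted against by 115 genes above 3 times the median of the others, fewer than the 202 of a bleomycin library, where genes raised by treatment mix in. Set against control libraries, a comparison chosen after these values, 115 exceeded the 11 to 27 of the others. Genes at 0 reads fell from 27.3% of those with a median of 10 to 50 reads to 0.035% at 500 or more, so low complexity may still account for part of it and stays open. No biological explanation was tested for a single library, and the library was kept, with its omission among the alternatives.

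AT2G04900, which overlaps the start of SCL21, was at 73.4 and 92.6 CPM in Col-0 control and bleomycin and at 0 and 2 reads in the triple mutant. Its 6.95 times higher CPM than SCL21 in Col-0 rests on the assignment of reads by Salmon and does not test whether reads are shared with SCL21. Shared reads would be split into fractional counts, but the counts of both loci were whole within 0.001 in 5 of 6 Col-0 libraries and 0.0387 off in the other, while those of the transcripts of AT2G04900 were split in 6 of 6, which argues against reads shared with SCL21 as the cause. A change confined to the mutated locus could account for it, as of the 30 measured neighbours of the 3 mutated genes 1 was called, namely this gene. The pattern was known when the test was written, so it decides nothing. The form of the mutations is not given in the sources used here.

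DESeq2 called 13 genes in both genotype comparisons, among them PAT1, SCL5, SCL21, AT2G04900, AT1G64795, AT5G35940 and CLE5. The last was at 16.4 and 7.24 CPM in Col-0 control and bleomycin and 29.4 and 14.5 in the triple mutant (edgeR adjusted p = 0.362 and 0.121).

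Other splits of the 6 libraries compared gave at most 0 genes for bleomycin in Col-0 (1455 in the real split), 0 for bleomycin in the triple mutant (1727) and 0 for the genotype in control (6), and 2 for the genotype after bleomycin (6). In each the real split was 1 of 10, which is too few for a share under 0.05. After bleomycin, where numbers pair the samples, the other splits that part all 3 pairs gave at most 0 genes and the 6 that keep a pair together at most 2. For the interaction the real split gave 0 genes, so 30 of 30 splits, the real one included, reached that count by construction. The highest gave 1 gene, and this comparison decides nothing.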
